A study of Danio rerio with 12 samples.

How the data were processed

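RNA-seq was made from photoconverted endothelial end cells and macrophages of zebrafish larvae. Per the labels' protocols, a laser switched the colour of a fluorescent protein, Dendra2 under the endothelial flk1 promoter or Kaede under the leukocyte coro1a promoter. About 80 cells in 20 animals were converted, heads were dissected and dissociated with trypsin, and cells were collected by flow sorting. Libraries were made with Smart-seq2, a full-length cDNA protocol for very small inputs, and read as PE100 on an Illumina HiSeq, per the labels' protocols. The 12 libraries formed 6 groups of 2, taken from the labelled cell type and lesion stage.

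Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.0 and DESeq 1.16.0 are named in the submitters' processing notes. The genome build and annotation release were not given in the sources used here, so no coordinates are printed. The authors deposited RPKM, reads scaled by gene length and by the reads of the library, for 33737 Ensembl gene IDs in each of the 12 libraries, per the file headers. The RPKM were not scaled between libraries beyond each library's reads in genes. In 6 further tables the authors deposited, for each pair of stages within a cell type, group means of counts divided by size factors. The authors' group means are a normalized signal, with size factors set anew in each deposited table. The same deposited tables hold the authors' p-values and adjusted p-values, and mark genes by a p under 0.05. The authors' deposited tables were used to recover reads, for the counts of genes they mark and for the protein entries behind some gene names.

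Reads per gene and library were recovered by combining the RPKM with the authors' group means. Of the values above 0, 100% came out whole within a tolerance of 0.05 reads in each library. Recovered reads in genes were 28277954 and 12283046 in macrophage control, 19599417 and 37292238 in macrophage arrival and 21285807 and 35419955 in macrophage traction. They were 19066891 and 31177640 in endothelial control, 26034263 and 39447004 in endothelial arrival and 23770327 and 28314860 in endothelial traction. The protocol as described in the labels names no molecular identifiers, so reads are not independent molecules and the floor of 3 reads used for a gene at 0 covers counting error only. With an input this small, the number of cells limits how precisely a low transcript is measured, whatever the number of reads. Where a gene is listed at 0, its RPKM are given and no fold, except against that floor.

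Genes were tested when they had at least 10 reads at the median depth in at least 2 libraries and at least 15 reads in all, which left 17613 genes. This filter on recovered reads was set after the tables were seen and before any model was fitted. The design fixed before the data were examined foresaw a count test for count tables and limma on RPKM otherwise. Since no deposited table holds counts per library, limma was the main test. Models were fitted with limma 3.58.1 in R 4.3.3 to log2(RPKM + 1), with a mean-variance trend and robust variances, over all 12 libraries with a mean for each of the 6 groups. Macrophages and endothelial cells were compared in a model with lesion stage and cell type. Stages were compared within each cell type, and the difference between cell types in the change from control was tested for arrival and for traction. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05 within each comparison. On this scale differences understate the change of genes with low RPKM. All tests were two-sided. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333, so none was run.

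The 29 gene lists, for cell types, pathways and signs of handling (heat shock, immediate early and mitochondrial genome), were written before the data were examined. A list was tested when at least 5 members passed the filter, which held for 28; oligodendrocyte markers had 3 tested members. Lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Beside it stand camera with an estimated correlation, whose adjusted p is called the estimated-correlation p, and fry, which asks whether members move on balance one way. Members were counted at p-values adjusted over all genes and adjusted over the list alone. Some genes belong to several lists, such as CXCR4 and mmp13a. In 38 of the 252 list tests the median, the mean and the direction of the test differed in sign, none of them among the 63 called.

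Names were found for 22156 of 33737 gene IDs and for 14011 of the 17613 tested, from a table of Ensembl names or from the zebrafish protein entry in the deposited tables. Symbols in upper case can stand for either zebrafish copy of a gene, and counted as members of a list that held the symbol alone or with the ending a or b. Reads of near-identical copies, such as globin, claudin and MPEG1 genes, and of overlapping or antisense genes may have been split by the authors' counting.

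Genes were named by a rule fixed before the data were examined. It took up to 10 higher and 10 lower genes with the largest difference among those with adjusted p under 0.05, a mean of at least 1 RPKM in the higher group and no overlap between the libraries compared. Genes with only a clone or identifier name were passed over (among passing genes, 3 higher and 4 lower in the comparison of cell types and 1 in macrophage traction against arrival, and among genes not passing 0 to 8 per direction and comparison). Where fewer than 5 passed in a direction, the genes of smallest p meeting the other conditions were named up to 5 and described as not passing. For the differences between cell types the rule took up to 5 each way, with no overlap between stages in at least 1 cell type. Up to 4 members of smallest p were taken from lists that were called or held passing members. The genes kdrl, coro1a, cdh5, mpeg1 and those of Rac1 and PI3K were given whatever their result. The gene si:rp71-1c10.11, stab1 and the 2 lists drawn in a plot were picked after their values were seen. The results of 1 of the 28 tested lists, which holds 1 of the 63 calls, and of 2 genes that the rule took are not reported here.

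Alternatives fixed before the data were examined were quantile normalization, no filter beyond an RPKM above 0 in any library (27142 genes), at least 1 RPKM in at least 2 libraries (15720 genes), a pseudocount of 0.1, each library left out in turn, the replicate number as a block, fits on the 6 libraries of a cell type or the 4 of a comparison, camera with an estimated correlation, and fry. Alternatives added after seeing the data were voom of limma on the recovered reads, RPKM recomputed without the most abundant gene, a fit without the 3 libraries with photoreceptor RNA, and the list tests under these settings.

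The steps were tested on simulated data. For 5000 genes in 6 libraries, 100% of the reads were recovered exactly. At the spread of these libraries 200 of 17613 genes were changed. Macrophage arrival against control called 0 of them at 4-fold, 1 at 16-fold and 25 at 64-fold. Macrophages against endothelial cells gave 0, 50 and 81. A 4-fold change of the glycolysis and hypoxia list in macrophage arrival gave a camera adjusted p of 1.06e-04 and called 0 other lists. Exchanged real libraries called 2 to 12, so false calls are not gauged. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.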

Results

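RNA was sequenced from photoconverted cells of zebrafish larval heads, in 12 Smart-seq2 libraries that formed 6 groups of 2. The study's title concerns the repair of ruptured brain vessels by macrophages that adhere to the vessel ends and pull on them. Each library came from macrophages or from endothelial end cells at 1 of 3 lesion stages: an uninjured control, the arrival of a macrophage and its traction. Reads assigned to genes ran from 12283046 in macrophage control replicate 2 to 39447004 in endothelial arrival replicate 2. Between 8929 genes (endothelial arrival replicate 1) and 17011 genes (macrophage traction replicate 2) had at least 1 read. A single unnamed gene, ENSDARG00000080337, took from 6.49% of these reads in macrophage traction replicate 2 to 41.7% in endothelial arrival replicate 1. Pairs of values per group are from 2 libraries, written replicate 1 first, and differences are on the log2(RPKM + 1) scale with their SE. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples. Where the call of a list ended without some of the libraries, with no filter or with quantile normalization, the adjusted p obtained there follows in parentheses. The percent left of the list's mean difference is added where this moved by over 1.5 times, negative where the direction turned.

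Macrophage and endothelial libraries carried different marker genes. The summed RPKM of 35 macrophage marker genes was 4950.5 to 21181 in the 6 macrophage libraries. It was 1.4 to 34.8 in 5 endothelial libraries and 2464 in endothelial control replicate 2. Erythroid markers summed to 18669 to 66202 RPKM in 5 endothelial libraries, 23.3 in endothelial arrival replicate 1 and at most 139 in macrophages. Photoreceptor and lens markers reached 44580.3 RPKM in endothelial arrival replicate 2, 70875 in endothelial traction replicate 1 and 5289 in macrophage traction replicate 1, against at most 271 elsewhere (the first 3 are called the photoreceptor libraries). Endothelial markers (32 genes) summed to 610.1 and 345 RPKM in these endothelial libraries, 1667 to 5211 in the other 4 and at most 399 in macrophages.

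**Figure D1:**
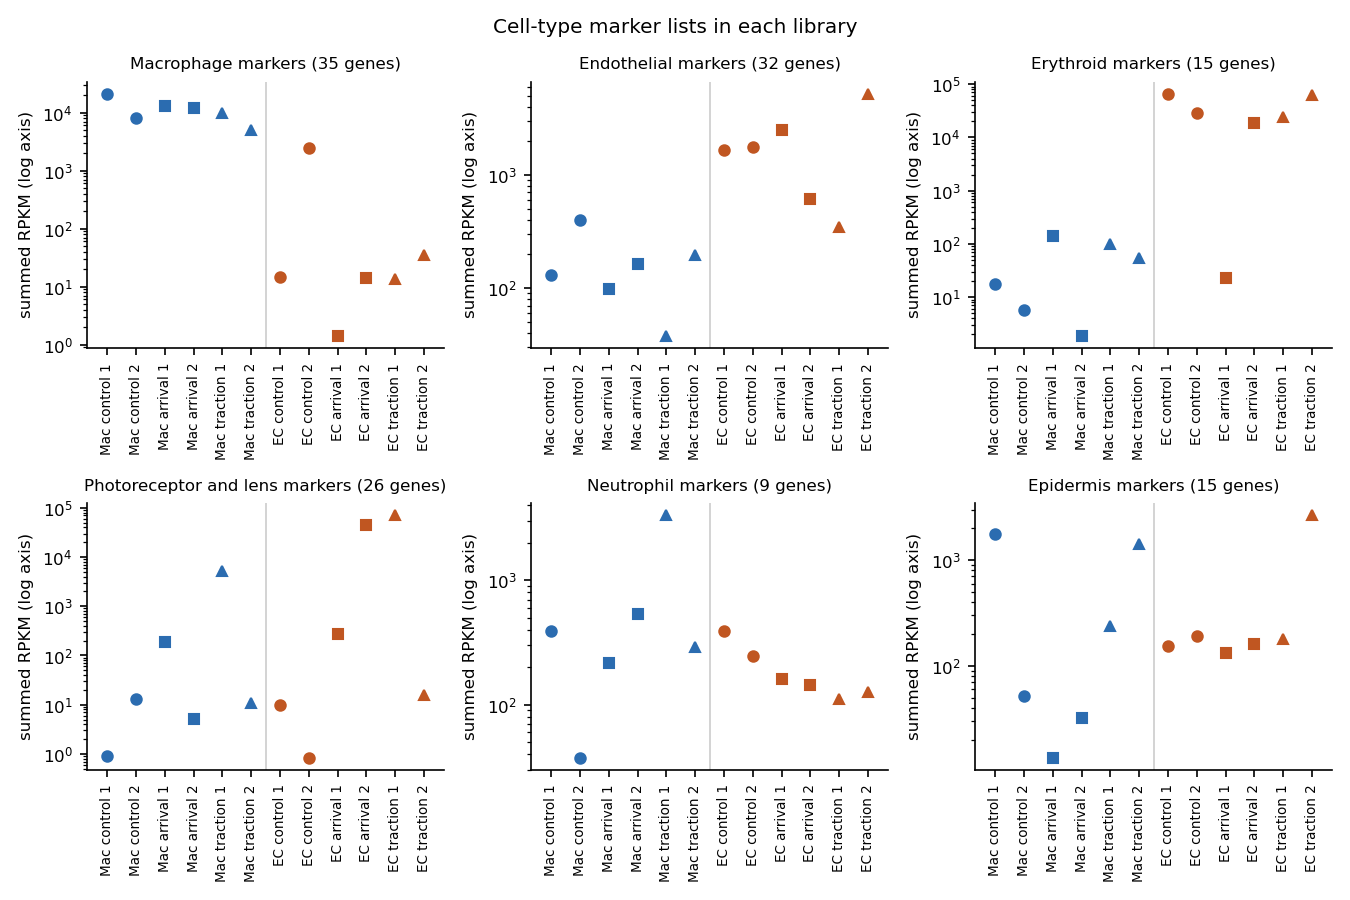
Summed RPKM (log axis) of the genes of 6 cell-type marker lists in each of the 12 libraries. Macrophage libraries (Mac) are in blue, endothelial libraries (EC) in orange, circles for control, squares for arrival and triangles for traction. Erythroid markers lie at 18669 or more in 5 endothelial libraries and at 139 or less in the 6 macrophage libraries.

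Replicates of 1 group correlated no more closely than other libraries of the same cell type. Spearman correlations of log2(RPKM + 1) across the 17613 tested genes, which are not independent replicates, were 0.35 to 0.522 within the 6 groups (median 0.37). They were 0.282 to 0.6 between groups of 1 cell type (24 pairs, median 0.415) and 0.169 to 0.481 between cell types (36 pairs, median 0.303).

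The comparison of macrophages with endothelial cells asked how the sorted populations differed. Among the genes named by rank, a chemokine gene and apolipoprotein genes were higher in macrophages, and claudin genes and SOX7 were higher in endothelial cells. Macrophage marker and lysosome genes were higher in macrophages as groups (estimated-correlation p = 0.00419 and 0.0151). ccl34b.1 (ENSDARG00000093608), a chemokine gene, stood at 2459 to 22544 RPKM in macrophages and 0.476 to 10.3 in endothelial cells (6 libraries each), a log2 difference of 11.66 ± 0.78 (SE). The apolipoprotein genes apoc1 (ENSDARG00000092170) and apoeb (ENSDARG00000040295) were higher in macrophages by 10.17 ± 0.91 and 9.65 ± 0.96, and the transcription factor gene mafbb (ENSDARG00000070542) by 8.70 ± 0.97. The tight-junction genes annotated CLDN5 (ENSDARG00000014059 and ENSDARG00000043716) gave log2 differences of -8.06 ± 1.02 and -6.55 ± 1.04, and the endothelial transcription factor gene SOX7 (ENSDARG00000030125) gave -7.27 ± 1.04. These genes passed with limma adjusted p values of 3.15e-10 to 2.59e-04 and no overlap between the 6 macrophage and the 6 endothelial libraries. In all, limma called 497 of 17613 genes, 378 higher and 119 lower in macrophages. Voom called 1124, with 471 genes called by both. Voom did not call ccl34b.1 (adjusted p = 0.313) or apoeb (adjusted p = 0.193).

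Other genes named by rank were c1ql1 (ENSDARG00000043436), havcr1 (ENSDARG00000040178), ctsl.1 (ENSDARG00000003902), lgals3bp.1 (ENSDARG00000040528), SLC7A7 (ENSDARG00000055226) and ccl34a.4 (ENSDARG00000090873) on the macrophage side, with log2 differences of 8.72 to 10.26. On the endothelial side they were tnfrsf9a (ENSDARG00000060498), SLC16A1 (ENSDARG00000016963), HLX (ENSDARG00000009134), krt18a.1 (ENSDARG00000018404), WASF3 (ENSDARG00000062948), 1 of the CXCR4 genes (ENSDARG00000057633) and foxf2b (ENSDARG00000070389), at -6.89 to -5.99. Of the reporter genes of the sorted lines, kdrl (ENSDARG00000015815), the vascular endothelial growth factor receptor gene also called flk1, stood at 11.4 to 97.3 RPKM in endothelial cells and at most 0.0755 in macrophages (-4.98 ± 0.999, limma adjusted p = 0.00342). CORO1A (ENSDARG00000054610), an actin-binding protein gene of leukocytes, stood at 255 to 1022 RPKM in macrophages and at most 5.59 in 5 endothelial libraries, but at 704 in endothelial control replicate 2 (6.78 ± 1.22, limma adjusted p = 0.00115, and 0.0756 without the photoreceptor libraries). The vascular cadherin gene cdh5 (ENSDARG00000075549, -5.04 ± 1.12, adjusted p = 0.00897) and the macrophage gene MPEG1 (ENSDARG00000055290, 7.76 ± 1.01, adjusted p = 2.11e-05) also passed.

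Among the fixed gene lists, all 30 tested macrophage markers were above 0 in this comparison (median log2 difference 5.64). Of these, 23 passed over all genes and 27 adjusted over the list alone (camera adjusted p = 1.67e-44, estimated-correlation p = 0.00419). Lysosome and phagocytosis genes were higher as well, with 21 of 50 passing and 32 adjusted over the list alone, among them the cathepsin gene CTSB (ENSDARG00000055120, 6.09 ± 0.87) and the prosaposin gene PSAP (ENSDARG00000013968, 5.26 ± 0.91) (camera adjusted p = 3.75e-21, estimated-correlation p = 0.0151). Of the 63 list calls in all comparisons only these held with an estimated correlation. Endothelial markers were lower in macrophages, with 11 of 29 passing and 18 adjusted over the list alone, against 1 higher by either adjustment (camera adjusted p = 4.28e-19, estimated-correlation p = 0.0612). That gene was stab1 (ENSDARG00000076484), a scavenger receptor gene, higher in macrophages by 4.36 ± 1.09 (limma adjusted p = 0.0216) and singled out after its value was seen. Endothelial junction genes were lower in 9 of 30 (10 lower and 1 higher adjusted over the list alone), with camera adjusted p = 1.26e-11 and estimated-correlation p = 0.0612. Angiogenesis, VEGF and Notch genes were lower in 6 of 56 and 15 adjusted over the list alone, including ANGPT2 (ENSDARG00000014946, -6.49 ± 1.204), with camera adjusted p = 9.75e-07 and estimated-correlation p = 0.179. Erythroid markers were lower in 7 of 13 and 9 adjusted over the list alone, led by the globin gene hbae3 (ENSDARG00000079305, -8.88 ± 1.2, not called by voom, adjusted p = 0.72), with camera adjusted p = 2.32e-15 and estimated-correlation p = 0.0631.

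Inflammatory genes were higher in macrophages, with 9 of 35 passing higher and 1 lower (12 and 1 adjusted over the list alone), led by ccl34a.4 (8.72 ± 0.93) and tnfb (ENSDARG00000013598, 7.85 ± 1.001), a tumour necrosis factor gene (camera adjusted p = 1.6e-07, estimated-correlation p = 0.201). Actin and actomyosin genes had 10 of 62 higher and 2 lower (13 and 2 adjusted over the list alone), among them the profilin gene pfn1 (ENSDARG00000088091, 6.24 ± 1.02, with a voom adjusted p of 0.598; camera adjusted p = 0.00635, estimated-correlation p = 0.384). Immediate early genes (4 of 31 higher; 9 higher and 1 lower adjusted over the list alone) and interferon and antigen presentation genes (1 of 21 higher, 2 adjusted over the list alone) had camera adjusted p values of 6.35e-05 and 0.0127, and adjusted p = 0.384 and 0.179 with an estimated correlation. Lower in macrophages were neuron markers (median -0.98, camera adjusted p = 1.84e-04, estimated-correlation p = 0.345) and photoreceptor and lens markers (-1.68, 1.84e-04 and 0.493), neither with a member passing. Glycolysis and hypoxia genes were lower (median -0.24, 1 of 34 passing and 2 adjusted over the list alone; camera adjusted p = 0.0171, estimated-correlation p = 0.493), as were genes of the mitochondrial genome (-0.34, none of 13 passing, 0.0209 and 0.663).

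Of the lists without a call, heme and iron genes had 5 of 24 members higher in macrophages (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.067), led by the heme oxygenase gene HMOX1 (ENSDARG00000027529, 6.67 ± 0.92) and the iron exporter gene slc40a1 (ENSDARG00000000241, 6.13 ± 1.08). Cell adhesion and integrin genes had 6 of 54 higher, including itgb2 (ENSDARG00000016939, 4.98 ± 1.08), and 5 lower (8 and 6 adjusted over the list alone; camera adjusted p = 0.846). Matrix, wound and growth factor genes had 4 of 52 higher, including plaua (ENSDARG00000075265, 6.77 ± 1.03), and 2 lower (8 and 7 adjusted over the list alone; camera adjusted p = 0.998). Single members also passed higher over all genes in the mural (rgs5b, ENSDARG00000017860, list camera adjusted p = 0.812), mesenchyme (LUM, ENSDARG00000045580, 0.358), oxidative phosphorylation (cox8b, ENSDARG00000097209, 0.289) and p53 and apoptosis lists (GADD45B, ENSDARG00000013576, 0.278). The keratin gene krt8 (ENSDARG00000058358) of the epidermal markers was lower adjusted over the list alone (0.17). The genes annotated as Rac1 and PI3K subunits, which were to be given whatever their result, did not pass as single genes: rac1a (ENSDARG00000074849) stood at 0.0389 to 68.5 RPKM in macrophages and 13.4 to 65.5 in endothelial cells (-0.25 ± 1.02, limma adjusted p = 0.945). The smallest adjusted p among the other tested members of this group was 0.246, for PIK3CB (ENSDARG00000075253, 2.80 ± 1.09). Without macrophage control replicate 2 the glycolysis (0.132, 45.8%) call, without macrophage arrival or traction replicate 2 the mitochondrial (0.105, 62.6% and 0.217, 63.6%) call, and without endothelial control replicate 1 the glycolysis (0.0526) and mitochondrial (0.088) calls ended. Without endothelial control replicate 2 the glycolysis (0.0697, 54.7%) call, without endothelial arrival replicate 1 the mitochondrial (0.308, 39.6%) call, without endothelial arrival replicate 2 the actin (0.0694) and interferon (0.0694) calls, and without endothelial traction replicate 1 the photoreceptor (0.076, 42.8%) call ended. Without endothelial traction replicate 2 the mitochondrial (0.0873) call, without the photoreceptor libraries the actin (0.426), interferon (0.0616), photoreceptor (0.388, 13.3%) and immediate early (0.0616) calls ended, and with quantile normalization the mitochondrial (0.0685) call ended. Among the named genes, the calls of LUM without macrophage control replicate 1 (0.0617) and rgs5b without macrophage arrival replicate 2 (0.0609) or traction replicate 1 (0.0581) ended. Without the photoreceptor libraries those of pfn1 (0.0614), itgb2 (0.168), cox8b (0.177), GADD45B (0.143), LUM (0.192) and rgs5b (0.342) ended. With no filter those of GADD45B (0.0621), LUM (0.0589) and rgs5b (0.101) ended. Without macrophage arrival replicate 2 the number of genes called was 301 (227 higher, 74 lower), and without the photoreceptor libraries it was 176 (114 and 62).

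Arrival was set against control in macrophages to ask how macrophages at a lesion differed from those of uninjured larvae. Glycolysis and hypoxia genes were higher at arrival as a group, and epidermal marker genes were lower (estimated-correlation p = 0.996, as for the other 3 called lists). f3b (ENSDARG00000005673), a tissue factor gene, stood at 88.6 and 291 RPKM at arrival and 0 and 0.0602 in control (7.30 ± 1.69). g0s2 (ENSDARG00000078859), an inhibitor of lipolysis, stood at 0 and 0.067 RPKM at arrival and 310.4 and 907 in control (-9.01 ± 1.75). Neither gene passed over all genes with limma (adjusted p = 0.867 and 0.625). Adjusted over the list alone, 2 of 52 matrix, wound and growth factor genes passed, f3b among them (camera adjusted p = 0.785).

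With limma 0 of 17613 genes passed between macrophage arrival and control, 732 had an unadjusted p under 0.05 (881 would by chance) and voom called 136 higher and 76 lower. The other genes named by smallest p, none passing, were MATK (ENSDARG00000074670, 7.51 ± 1.70), SLC43A3 (ENSDARG00000057949, 6.97 ± 1.63) and il21 (ENSDARG00000067847, 6.39 ± 1.65) on the higher side. Those on the lower side were vtg8 (ENSDARG00000092028, -5.04 ± 1.304), RAPGEF6 (ENSDARG00000010945, -5.07 ± 1.33) and SOSTDC1 (ENSDARG00000056021, -4.40 ± 1.19). Of the 34 glycolysis and hypoxia genes 26 were above 0, with a median of 1.56 and none passing by either adjustment (camera adjusted p = 1.18e-04). Examples were the glycolytic enzyme gene pgam1a (ENSDARG00000005423, 143 and 351 RPKM at arrival, 23.2 and 12.21 in control) and the hypoxia-induced gene ANKRD37 (ENSDARG00000056376, 66.1 and 39.3 RPKM, listed at 0 in control). Oxidative phosphorylation genes (median 0.96, 42 of 52 above 0, camera adjusted p = 0.0212) and heat shock and unfolded protein genes (median 0.90, 26 of 36 above 0, camera adjusted p = 0.0425) were also higher, with no member passing by either adjustment. Genes of the mitochondrial genome were lower (median -0.67, 12 of 13 below 0, none passing by either adjustment, camera adjusted p = 0.0443). Epidermal markers were lower, with 9 of 10 below 0 and a median of -3.29, and 1 passed adjusted over the list alone, TP63 (ENSDARG00000044356, 0.584 and 0 RPKM at arrival, 16.7 and 51.5 in control; camera adjusted p = 7.7e-05). Their summed RPKM was 1767 and 51.7 in control and 13.7 and 32.1 at arrival. The smooth muscle actin gene acta2 (ENSDARG00000045180), at 1.32 and 2.51 RPKM at arrival and 0 in control, passed adjusted over the mural cell list alone (1 of 9, camera adjusted p = 0.595). Genes called without a library of either group are not given here, since 1 library then stands for that group. Without control replicate 1 the mitochondrial (0.474), epidermal (0.72, 1.58%) and heat shock (0.0586) calls, without control replicate 2 the mitochondrial (0.0782), oxidative phosphorylation (0.392, -50.1%) and heat shock (0.392, 61.8%) calls, and without arrival replicate 1 the oxidative phosphorylation (0.426) call ended. Without arrival replicate 2 the mitochondrial (0.742, 42%) and heat shock (0.742, 54.4%) calls, and without endothelial traction replicate 1 or 2 the mitochondrial (0.06 and 0.0585) call ended. Without the photoreceptor libraries the oxidative phosphorylation (0.0683) call ended. With no filter the mitochondrial (0.131) and heat shock (0.103) calls ended. In the 4 libraries alone the mitochondrial (0.117), oxidative phosphorylation (0.0521) and heat shock (0.0521) calls ended.

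Traction against control in macrophages, a comparison that shares its control libraries with the arrival comparison, asked how macrophages differed while pulling on the vessel ends. Glycolysis and hypoxia, heat shock, inflammatory, heme and iron and oxidative phosphorylation genes were higher as groups, as were neutrophil and radial glia markers, and genes of the cell cycle and of the mitochondrial genome were lower. These lists had estimated-correlation p values of 0.626 to 0.834. The hypoxia-induced genes VEGFA (ENSDARG00000034700) and EGLN3 (ENSDARG00000032553), which encode an angiogenic growth factor and an oxygen-sensing hydroxylase, stood at 19.6 and 10.01 and at 65.4 and 103 RPKM in traction and at most 0.302 RPKM in control (3.72 ± 1.09 and 6.35 ± 1.89). HMOX1 stood at 3262 and 819 RPKM against 290.2 and 141 in control (3.01 ± 1.52), and the ferritin gene fthl27 (ENSDARG00000031776) at 5679 and 3712 against 802 and 648 (2.67 ± 0.90). negaly6 (ENSDARG00000089123) and APOD (ENSDARG00000057437), an apolipoprotein gene, were listed at 0 in control and stood at 182 and 533 and 47.2 and 123 RPKM in traction. With limma 0 genes passed, the smallest adjusted p was 0.0607, 1049 genes had an unadjusted p under 0.05, and voom called 409 higher and 58 lower. Over all tested genes the median difference was 0.26.

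Of 34 glycolysis and hypoxia genes, 30 were above 0 in traction against control (median 2.47), and 3 passed adjusted over the list alone, pgam1a, VEGFA and EGLN3 (camera adjusted p = 5.79e-06, estimated-correlation p = 0.626). Heat shock and unfolded protein genes had 30 of 36 above 0 (median 1.77) and 1 passing adjusted over the list alone, the chaperone gene hsp70l (ENSDARG00000055723) at 73.1 and 495 RPKM against 0.0154 and 0.106 (camera adjusted p = 1.78e-04, estimated-correlation p = 0.7). Inflammatory genes had 29 of 35 above 0 (median 1.33), and 2 passed adjusted over the list alone (camera adjusted p = 0.0079, estimated-correlation p = 0.703). They were the immune-response gene irg1l (ENSDARG00000062788), at 25.9 and 13.9 RPKM and 0 in control, and the collagenase gene mmp13a (ENSDARG00000012395), at 426 and 7.01 and 0. Heme and iron genes (median 1.22, 21 of 24 above 0, none passing by either adjustment) had a camera adjusted p of 0.0123, estimated-correlation p = 0.7. For oxidative phosphorylation genes (median 1.35, 44 of 52 above 0, none passing by either adjustment) these were 0.0123, estimated-correlation p = 0.834. The lower groups were the mitochondrial genome (median -1.02, 12 of 13 below 0; camera adjusted p = 2.97e-04, estimated-correlation p = 0.738) and the cell cycle (median -0.54, 33 of 54 below 0; camera adjusted p = 0.0417, estimated-correlation p = 0.788). Neither had a member passing, and mki67 (ENSDARG00000091150), a proliferation marker, stood at 0 and 1.4 RPKM against 16.5 and 25.2.

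Neutrophil markers were above 0 in 8 of 8 (median 4.22) with 3 passing adjusted over the list alone (camera adjusted p = 4.5e-05, estimated-correlation p = 0.626), and summed to 3336 and 293 RPKM in traction against 389 and 37.5 in control. The granule enzyme gene lyz (ENSDARG00000057789) stood at 1447 and 1.22 RPKM and at 0 in control. Radial glia markers were above 0 in 14 of 17 (median 1.499), none passing by either adjustment, with the Notch target gene her4.1 (ENSDARG00000056732) at 118 and 20.8 RPKM and 0 in control (camera adjusted p = 0.0123, estimated-correlation p = 0.738). Lists without a call also held members passing adjusted over the list alone: 4 of 52 matrix, wound and growth factor genes (among them f3b, mmp13a and the fibronectin gene FN1, ENSDARG00000006526; camera adjusted p = 0.409), cd74b (ENSDARG00000036628) of the macrophage markers (85.8 and 11.05 RPKM, 0 in control; camera adjusted p = 0.117) and of the interferon and antigen presentation genes (0.933), and TP63 on the lower side of the epidermal markers (0.714). In traction f3b stood at 105 and 282 RPKM. Also named by smallest p were krt1-c5 (ENSDARG00000026979, 7.25 ± 1.54), vsig8a (ENSDARG00000054050, 5.80 ± 1.301) and MATK (7.46 ± 1.70) on the higher side. The lower side held a gene annotated 5S_rRNA (ENSDARG00000083941, -8.14 ± 1.72), SOSTDC1 (-4.40 ± 1.19), spaca6 (ENSDARG00000097454, -3.62 ± 0.99) and entpd2a.2 (ENSDARG00000033953, -4.11 ± 1.13). Genes called without a library of either group are not given here, since 1 library then stands for that group. Without traction replicate 1 or the photoreceptor libraries that is traction replicate 2, with the most genes at 1 RPKM or more (12938). Without control replicate 1 the inflammatory (0.169), heme (0.0781) and cell cycle (0.809, -50.4%) calls, without control replicate 2 the oxidative phosphorylation (0.356, -6.39%) and radial glia (0.198) calls, and without traction replicate 1 the oxidative phosphorylation (0.667), inflammatory (0.0853), radial glia (0.0853) and cell cycle (0.13, -25.9%) calls ended. Without traction replicate 2 the mitochondrial (0.338, 49.3%), heme (0.117, 48.6%) and cell cycle (0.0715, 226%) calls and without the photoreceptor libraries the oxidative phosphorylation (0.842), inflammatory (0.304), heme (0.0756, 151%), cell cycle (0.23, -25.9%) and neutrophil (0.0654, 45%) calls ended. With no filter the cell cycle (0.0618) call ended.

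**Figure D2:**
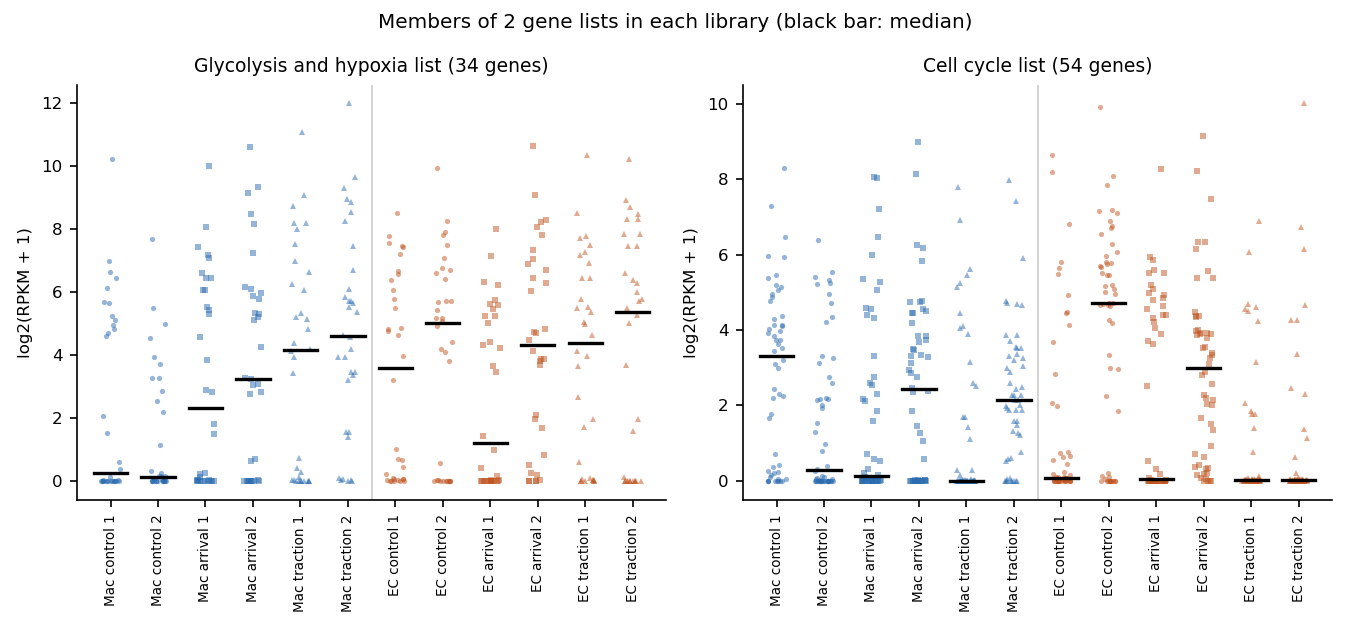
Log2(RPKM + 1) of each tested gene of the glycolysis and hypoxia list (34 genes) and of the cell cycle list (54 genes) in each of the 12 libraries, 1 point per gene, with a black bar at the median. For glycolysis and hypoxia the median is 0.25 and 0.11 in macrophage control, 2.31 and 3.24 at arrival and 4.16 and 4.60 in traction, and for the cell cycle it is 0.07 and 4.72 in endothelial control, 0.04 and 2.99 at arrival and 0.02 and 0.02 in traction, and between 0 and 3.32 in the macrophage libraries.

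Traction against arrival in macrophages asked what differed between the stages at a lesion. A single gene passed with limma, si:rp71-1c10.11 (ENSDARG00000096721), named after its values were seen. It stood at 927 and 5126 RPKM in traction and was listed at 0 in both arrival libraries (11.09 ± 1.62, limma adjusted p = 0.0393). Its traction mean was 12858 times a floor of 3 reads per library. The next genes that have a name, none passing, were negaly6 (8.29 ± 1.47), APOD (6.27 ± 1.33), krt1-c5 (7.03 ± 1.54), phlda2 (ENSDARG00000042874, 8.19 ± 1.78) and vsig8a (5.77 ± 1.301) on the higher side. The lower ones were setd6 (ENSDARG00000043986, -4.50 ± 1.2), MAP2K7 (ENSDARG00000008279, -4.46 ± 1.19), parp14rs1 (ENSDARG00000040445, -2.77 ± 0.82), pgbd4 (ENSDARG00000079328, -2.78 ± 0.85) and GINS2 (ENSDARG00000002304, -4.93 ± 1.52). In all 591 genes had an unadjusted p under 0.05, and voom called 281 higher and 24 lower. Neutrophil markers were higher, with 7 of 8 above 0 (median 4.204) and 4 passing adjusted over the list alone (camera adjusted p = 2.21e-04), and so were epidermal markers, with 9 of 10 above 0 (median 4.06) and none passing by either adjustment (camera adjusted p = 2.42e-04). Both had an estimated-correlation p = 0.831. Their summed RPKM in traction was 3336 and 293 for neutrophil and 239.6 and 1405 for epidermal markers, against 218 and 537 and 13.7 and 32.1 at arrival. In lists without a call, members passing adjusted over the list alone were cd74b (macrophage markers, camera adjusted p = 0.0971; interferon genes, 0.232), irg1l and mmp13a (inflammatory, 0.362) and PDIA4 (ENSDARG00000018491, heat shock, 0.119), a protein disulfide isomerase gene at 85 and 110.3 RPKM against 0 at arrival, on the higher side and acta2 on the lower side (mural, 0.953). The 1 call ended (0 genes) under 6 other settings and without any 1 of the other 10 libraries. It held without either traction library and without the photoreceptor libraries, where traction rests on 1 library. Without traction replicate 1 the neutrophil (0.11, 36.7%) call and without traction replicate 2 the epidermal (0.0767) call ended. Without the photoreceptor libraries the epidermal (0.211) and neutrophil (0.233, 36.7%) calls ended.

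Arrival against control in endothelial cells asked how vessel end cells differed once a macrophage had reached them. Immediate early, neuron, radial glia and photoreceptor genes were higher as groups, and erythroid, lysosome and macrophage marker genes were lower. Each of these 7 lists had an estimated-correlation p = 0.859. The immediate early genes ATF3 (ENSDARG00000007823) and FOSB (ENSDARG00000055751) stood at 283 and 9.34 and at 127 and 18.6 RPKM at arrival against 0.0188 and 3.3 and 0.022 and 0.0202 in control (4.69 ± 1.75 and 5.62 ± 2.15). HSP90AA1 (ENSDARG00000024746), a chaperone gene, stood at 66.4 and 293 RPKM against 0 and 0.0419 (7.11 ± 1.70), and CYP1B1 (ENSDARG00000068934), a cytochrome P450 gene, was listed at 0 at arrival and stood at 128 and 97.1 RPKM in control (-6.81 ± 1.36). None passed, and limma called 0 genes (smallest adjusted p 0.824), while 719 genes had an unadjusted p under 0.05, and voom called 247 higher and 84 lower. The other genes named by smallest p were her2 (ENSDARG00000038205, 4.80 ± 1.159), NICOL1 (ENSDARG00000089877, 6.77 ± 1.65), en2b (ENSDARG00000038868, 5.14 ± 1.26) and QPCT (ENSDARG00000089717, 5.28 ± 1.31) on the higher side. Named on the lower side were CEBPB (ENSDARG00000042725, -7.32 ± 1.6), znfl2a (ENSDARG00000008333, -5.51 ± 1.25), cpn2 (ENSDARG00000044326, -6.45 ± 1.48) and GEMIN7 (ENSDARG00000041011, -7.04 ± 1.90).

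Erythroid markers were below 0 at endothelial arrival in all 13 (median -2.96), and 2 passed adjusted over the list alone, led by the globin gene hbae1.3 (ENSDARG00000089124) at 0.138 and 12.7 RPKM against 1059 and 303 (camera adjusted p = 1.48e-07). Their summed RPKM was 23.3 and 18669 at arrival and 66202 and 28786 in control. Photoreceptor and lens markers (median 3.05, 14 of 17 above 0, camera adjusted p = 2.68e-04) summed to 271 and 44580.3 RPKM at arrival. Radial glia markers (1.75, 16 of 17, 9.78e-04) and neuron markers (1.39, 17 of 24, 0.0118) were higher on the same measures, with the neuronal gene ELAVL4 (ENSDARG00000045639) at 20.1 and 16.1 RPKM and 0 in control. Immediate early genes were above 0 in 22 of 31 (median 0.90, camera adjusted p = 0.0118). Lysosome genes were below 0 in 36 of 50 (median -1.164, camera adjusted p = 0.00149), among them CD63 (ENSDARG00000025147) at 42.9 and 102 RPKM against 609 and 595, and macrophage markers in 22 of 30 (median -0.34, camera adjusted p = 0.0017). These macrophage markers summed to 2464 RPKM in control replicate 2 and at most 14.5 in the other 3 libraries. Outside the erythroid list no member of these lists passed by either adjustment. Adjusted over the list alone, rgs5b of the mural markers (0 at arrival, 72.5 and 40.5 RPKM in control; camera adjusted p = 0.663) and CEBPB of the inflammatory genes (0.145) also passed. Without the photoreceptor libraries arrival rests on 1 library, replicate 1, so genes called there are not given here. Without control replicate 1 the immediate early (0.227, 45.5%) call, without control replicate 2 the photoreceptor (0.0639), radial glia (0.0575), neuron (0.722, 49.4%), lysosome (0.0575, 60.7%) and macrophage (0.474, 9.78%) calls, and without arrival replicate 1 the immediate early (0.93, 64.4%) call ended. Without arrival replicate 2 the photoreceptor (0.244, 33.5%), radial glia (0.445, 27.6%), neuron (0.507, 24.9%) and macrophage (0.188) calls and without the photoreceptor libraries the radial glia (0.69, 27.6%), neuron (0.599, 24.9%) and macrophage (0.434) calls ended.

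Traction against control in endothelial cells asked how they differed while being pulled. Cell cycle genes were lower as a group (48 of 54 below 0, median -1.71, camera adjusted p = 5.28e-06, estimated-correlation p = 0.913). None passed by either adjustment. List medians of log2(RPKM + 1) were 0.07 and 4.72 in control, 0.02 and 0.02 in traction, where endothelial markers had 0.12 and 5.61. The mitotic gene BIRC5 (ENSDARG00000075621) stood at 0 in traction and 55.3 and 53 RPKM in control (-5.78 ± 1.82). mki67 stood at 0 and 0.0302 against 49 and 45 (-5.56 ± 1.76). snai1a (ENSDARG00000056995) stood at 18.1 and 15.7 RPKM against 0 and 0.0157 (4.15 ± 1.08). ANXA1 (ENSDARG00000026726) stood at 55.5 and 265 against 0 and 0.0195 (6.92 ± 1.83). With limma 0 genes passed, the smallest adjusted p was 0.979, 669 genes had an unadjusted p under 0.05, and voom called 148 higher and 169 lower. Further genes named by smallest p were HSP90AA1 (6.53 ± 1.70), FRMD1 (ENSDARG00000078741, 5.11 ± 1.38) and ARMC1 (ENSDARG00000013861, 5.94 ± 1.61) on the higher side. Lower by this rule were CYP1B1 (-6.78 ± 1.36), cpn2 (-6.95 ± 1.48), znfl2a (-5.43 ± 1.25), pclaf (ENSDARG00000097691, -7.25 ± 1.77) and mrpl24 (ENSDARG00000019222, -6.61 ± 1.73).

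Photoreceptor and lens markers were higher in endothelial traction than in control (16 of 17 above 0, median 4.78, camera adjusted p = 1.16e-08, estimated-correlation p = 0.913), and summed to 70875 and 15.8 RPKM. Mesenchyme and cartilage markers were above 0 in 10 of 11 (median 2.003, camera adjusted p = 0.00344, estimated-correlation p = 0.913), with the cartilage matrix gene MATN1 (ENSDARG00000030215) at 113 and 0 RPKM, and summed to 563 and 1.4 RPKM. Inflammatory genes were below 0 in 24 of 35 (median -0.29), and 2 passed adjusted over the list alone, CEBPB and the chemokine receptor gene CXCR4 (ENSDARG00000041959) at 0.101 and 0.0844 RPKM against 84 and 255 (camera adjusted p = 0.0136, estimated-correlation p = 0.913). Macrophage markers were below 0 in 20 of 30 (median -0.20, camera adjusted p = 0.0255, estimated-correlation p = 0.954) and summed to 13.7 and 34.8 RPKM in traction against 14.5 and 2464 in control. Of the mural markers rgs5b (0.0408 and 0.0686 RPKM in traction) passed adjusted over the list alone (camera adjusted p = 0.919). In the photoreceptor, mesenchyme and macrophage lists no member passed by either adjustment. Without control replicate 2 the inflammatory (0.423, 32.9%), cell cycle (0.423, 27%), macrophage (0.82, 6.14%) and mesenchyme (0.423) calls and without traction replicate 1 the photoreceptor (0.808, 4.79%), inflammatory (0.262), macrophage (0.104) and mesenchyme (0.808, -23.7%) calls ended. Without traction replicate 2 the macrophage (0.0598) call and without the photoreceptor libraries the photoreceptor (0.78, 4.79%), inflammatory (0.481), macrophage (0.296) and mesenchyme (0.78, -23.7%) calls ended. With no filter the inflammatory (0.0661), macrophage (0.0511) and mesenchyme (0.0511) calls ended. In the 6 endothelial libraries alone the inflammatory (0.0858) call ended, and in the 4 libraries of the comparison the inflammatory (0.143) and macrophage (0.0821) calls.

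Traction against arrival in endothelial cells asked what differed between the lesion stages. Cell cycle, immediate early and radial glia genes were lower in traction as groups, and erythroid, mesenchyme and glycolysis genes were higher. All 6 lists had an estimated-correlation p = 0.77. The ribonucleotide reductase gene RRM2 (ENSDARG00000020711) was listed at 0 in traction and stood at 12 and 14 RPKM at arrival (-3.80 ± 2.04). The immediate early genes klf2a (ENSDARG00000042667) and klf2b (ENSDARG00000040432) stood at 0.618 and 6.77 and at 0.429 and 0.039 RPKM in traction against 368 and 15.5 and 63.9 and 20.2 at arrival (-4.46 ± 2.08 and -4.93 ± 1.99). The Notch target gene HES1 (ENSDARG00000006514) stood at 0 and 0.023 RPKM against 386 and 66 (-7.31 ± 1.81). With limma 0 genes passed, the smallest adjusted p was 1, 595 genes had an unadjusted p under 0.05, and voom called 46 higher and 228 lower. Also named by smallest p were snai1a (4.13 ± 1.08), ANXA1 (6.94 ± 1.83), WNT4 (ENSDARG00000071208, 3.15 ± 0.86), anxa5b (ENSDARG00000016470, 6.51 ± 1.77) and hbae1.3 (6.95 ± 1.94) on the higher side. Those lower were CLIC2 (ENSDARG00000010625, -7.20 ± 1.49), her2 (-4.80 ± 1.159), en2b (-5.14 ± 1.26) and QPCT (-5.28 ± 1.31).

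Between endothelial traction and arrival 50 of 54 cell cycle genes were below 0 (median -1.69, camera adjusted p = 1.06e-04), 27 of 31 immediate early genes (median -1.18, 0.00136) and 14 of 17 radial glia markers (median -1.161, 0.0203). Erythroid markers were above 0 in 11 of 13 (median 2.31, camera adjusted p = 1.54e-04), with hbae1.3 and hbae1.1 (ENSDARG00000089475) passing adjusted over the list alone, and summed to 24139 and 61057 RPKM in traction against 23.3 and 18669. Mesenchyme markers were above 0 in 9 of 11 (median 1.64, 0.00712) and glycolysis and hypoxia genes in 22 of 34 (median 0.63, 0.0159). Outside the erythroid list no member of the 6 lists passed by either adjustment. Without the photoreceptor libraries each of these stages rests on 1 library, so genes called there are not given here. Without arrival replicate 1 the glycolysis (0.191, -32%), immediate early (0.75), mesenchyme (0.12, 36.5%) and erythroid (0.32, -5%) calls, without arrival replicate 2 the radial glia (0.951, -2.01%) call, and without traction replicate 1 the immediate early (0.226) and mesenchyme (0.387, -58.5%) calls ended. Without traction replicate 2 the glycolysis (0.178), radial glia (0.259, 64.5%) and erythroid (0.217, 46%) calls, with quantile normalization the glycolysis (0.0646) call, and without the photoreceptor libraries the radial glia (0.834, 33.5%) and mesenchyme (0.943, 4.95%) calls ended. In the 6 endothelial libraries alone the radial glia (0.0524) and mesenchyme (0.119) calls ended. In the 4 libraries of the comparison the radial glia (0.0875), mesenchyme (0.237) and glycolysis (0.0518) calls ended.

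The last comparisons asked whether the lesion stages changed macrophages and endothelial cells differently, as the difference of macrophage minus endothelial changes from control. For arrival, glycolysis and hypoxia, erythroid, lysosome, inflammatory, actin and macrophage marker genes had higher differences in macrophages, and epidermal and photoreceptor markers lower ones. The estimated-correlation p was 0.749 for macrophage and photoreceptor markers and 0.743 for the other 6 lists. Endothelial control replicate 2 held 2464 RPKM of macrophage markers. The adenosine receptor gene ADORA2B (ENSDARG00000002533) stood at 10.7 and 11.08 RPKM at arrival and 0.105 and 0 in control in macrophages, and at 0.0286 and 0 and 51.1 and 25.1 in endothelial cells (8.68 ± 2.25). ANKRD37 stood at 0 and 25.3 RPKM in endothelial cells at arrival and 217 and 103 in control (10.57 ± 2.54), and was the 1 glycolysis and hypoxia gene passing adjusted over the list alone. With limma 0 genes passed (smallest adjusted p 0.949), 629 had an unadjusted p under 0.05, and voom called 18 higher and 19 lower. Other genes named by smallest p were GEMIN7 (12.06 ± 2.69), cdkn1ca (ENSDARG00000010878, 9.71 ± 2.398) and rgs5b (8.63 ± 2.29) on the higher side. Genes of the lower side were g0s2 (-9.01 ± 2.48), COX4I2 (ENSDARG00000022509, -10.58 ± 3.10), UCHL1 (ENSDARG00000026871, -8.33 ± 2.62), neurod1 (ENSDARG00000019566, -11.28 ± 3.64) and ufm1 (ENSDARG00000043857, -6.95 ± 2.26). The camera adjusted p was 0.00187 for glycolysis and hypoxia (25 of 34 above 0), 3.98e-04 for erythroid (13 of 13), 0.0107 for lysosome (36 of 50), 0.0107 for inflammatory (28 of 35), 0.0194 for actin (38 of 62) and 0.0343 for macrophage marker genes (20 of 30). It was 0.00367 for epidermal (9 of 10 below 0) and 0.0107 for photoreceptor markers (14 of 17). Adjusted over the list alone, rgs5b of the mural markers (camera adjusted p = 0.304) passed as well. Without macrophage control replicate 1 the photoreceptor (0.0837), epidermal (0.455, 14.4%), inflammatory (0.103) and macrophage (0.0837) calls, without macrophage control replicate 2 the actin (0.202, 52.5%), photoreceptor (0.152), lysosome (0.152, 61.5%) and macrophage (0.153) calls, without macrophage arrival replicate 2 the actin (0.0964), photoreceptor (0.25), inflammatory (0.444, 49.6%), lysosome (0.281) and macrophage (0.444) calls, and without macrophage traction replicate 1 or 2 the macrophage (0.0624 and 0.0672) call ended. Without endothelial control replicate 2 the actin (0.154, 49%), photoreceptor (0.167), epidermal (0.0556), inflammatory (0.174, 39.3%), lysosome (0.0617) and macrophage (0.379, 23.4%) calls, without endothelial arrival replicate 1 the erythroid (0.0539, 33.1%) call, and without endothelial arrival replicate 2 the actin (0.411), photoreceptor (0.411, 29%), inflammatory (0.4) and macrophage (0.4) calls ended. Without the photoreceptor libraries the actin (0.53), inflammatory (0.383) and macrophage (0.483) calls and with quantile normalization the lysosome (0.0922) and macrophage (0.0925) calls ended. With no filter the actin (0.0639), photoreceptor (0.0726), inflammatory (0.0639), lysosome (0.0639) and macrophage (0.0726) calls ended.

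For traction, inflammatory, neutrophil, glycolysis and hypoxia and heat shock genes had higher differences in macrophages, and mesenchyme and photoreceptor markers lower ones. The photoreceptor markers had an estimated-correlation p = 0.832 and the other 5 lists of 0.705. Macrophage traction replicate 1 held 3336 RPKM of neutrophil markers and endothelial control replicate 2 held 2464 RPKM of macrophage markers. CXCR4 (ENSDARG00000041959) stood at 664 and 112 RPKM in traction and 21 and 1.7 in control in macrophages. It stood at 0.101 and 0.0844 and 84 and 255 in endothelial cells (12.23 ± 2.77). EGLN3 stood at 0.0727 and 2 RPKM in endothelial traction and 43.8 and 29.1 in endothelial control (10.71 ± 2.68). With limma 0 genes passed (smallest adjusted p 0.953), 739 had an unadjusted p under 0.05, and voom called 55 higher and 7 lower. The other genes named by smallest p were CLIC2 (9.28 ± 2.11), ADORA2B (9.72 ± 2.25), OAZ2 (ENSDARG00000045929, 10.01 ± 2.35) and mrpl24 (10.29 ± 2.45) on the higher side. The lower side gave glud1a (ENSDARG00000008816, -8.01 ± 2.30), the 5S_rRNA gene (-8.14 ± 2.43), KLF12 (ENSDARG00000015312, -7.82 ± 2.45), SERF2 (ENSDARG00000075881, -7.43 ± 2.33) and ANXA1 (-8.18 ± 2.58). Inflammatory genes were above 0 in 30 of 35 (median 2.27, camera adjusted p = 1.19e-04), with CXCR4 passing adjusted over the list alone, and neutrophil markers in 7 of 8 (median 5.54, 6.22e-04). Glycolysis and hypoxia genes were above 0 in 28 of 34 (median 2.09, camera adjusted p = 0.0136), with EGLN3 passing adjusted over the list alone, and heat shock genes in 27 of 36 (median 2.11, 0.0108). Mesenchyme markers were below 0 in 10 of 11 (median -3.43, camera adjusted p = 9.27e-04) and photoreceptor markers in 17 of 17 (median -2.08, 0.0136). Adjusted over the list alone, rgs5b of the mural markers (camera adjusted p = 0.709) and CXCR4 of the angiogenesis list (0.144) passed too, and no other member of the 6 lists did. Without macrophage control replicate 1 the photoreceptor (0.0593) call, without macrophage control replicate 2 the photoreceptor (0.114), glycolysis (0.114) and heat shock (0.0664) calls, and without macrophage traction replicate 2 the photoreceptor (0.546, -0.732%), glycolysis (0.064), heat shock (0.0854) and mesenchyme (0.064) calls ended. Without endothelial control replicate 2 the photoreceptor (0.175), glycolysis (0.114), heat shock (0.175) and mesenchyme (0.114) calls, without endothelial traction replicate 1 the photoreceptor (0.282, -103%), glycolysis (0.0836) and mesenchyme (0.299, 14.7%) calls, and without the photoreceptor libraries the photoreceptor (0.919, -2.1%), glycolysis (0.201), heat shock (0.0793), inflammatory (0.211), neutrophil (0.0787, 63.4%) and mesenchyme (0.231, 18.3%) calls ended. Without the photoreceptor libraries each traction group rests on 1 library. With no filter the photoreceptor (0.0788) call ended.

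The genes of the sorted lines and of Rac1 and PI3K did not pass as single genes between lesion stages. In endothelial cells kdrl stood at 42.7 and 77.8 RPKM in control, 97.3 and 15.4 at arrival and 11.4 and 15.2 in traction, and cdh5 at 75.4 and 18, 189.6 and 31 and 0.555 and 96.2. In macrophages CORO1A stood at 448 and 255 RPKM in control, 625 and 1022 at arrival and 557 and 450.5 in traction, and MPEG1 at 438 and 292, 479 and 1018 and 342 and 209. The gene rac1a stood at 55.5 and 0.0389, 59.9 and 53.7 and 68.5 and 57.4 RPKM in macrophages and at 13.4 and 26, 30.6 and 48.9 and 65.5 and 54 in endothelial cells over the same stages. Of these 14 tested genes the smallest limma adjusted p was 0.84, for pik3ap1 (ENSDARG00000078285), an adaptor gene of PI3K, between macrophage traction (5.7 and 4.08 RPKM) and control (0 in both libraries). Actin and actomyosin genes as a list (camera adjusted p at least 0.135) were not called in the 6 stage comparisons. Lists called in none of the 9 comparisons were muscle (lowest camera adjusted p 0.147), mural cell (0.304), cell adhesion and integrin (0.437), matrix, wound and growth factor (0.119) and p53 and apoptosis genes (0.102).

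In macrophages the authors' deposited tables gave 282 genes for arrival against control, 620 for traction against arrival and 603 for traction against control at p under 0.05, and 3, 3 and 0 at an adjusted p under 0.05. In endothelial cells the authors' deposited tables gave 294 genes for arrival against control, 354 for traction against arrival and 300 for traction against control at p under 0.05, and 0 at an adjusted p under 0.05 in each. Of the genes named here, g0s2 had an adjusted p of 0.0344 in the authors' deposited table of macrophage arrival against control, and negaly6 and PDIA4 had 9.37e-04 and 0.00426 in that of traction against arrival. These p-values rest on the authors' normalized counts.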

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

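The results given here are gene lists whose change from control differed between macrophages and endothelial cells by a camera test of that difference. The tests on photoreceptor RNA, and the fit without the 3 libraries that held it, were chosen after its levels had been seen. The test of carried-over reads was first made with the whole erythroid list and was narrowed to its globin genes after that value, past the same bound, had been seen. None of the 14 differences held with an estimated correlation between genes (adjusted p from 0.705 to 0.832) or by fry.

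At arrival, 8 lists differed. Glycolysis and hypoxia genes had a median log2 difference from control of 1.56 in macrophages and -0.02 in endothelial cells (adjusted p of the difference 0.00187). Inflammatory genes had medians of 0.96 and -0.01 (0.0107), where their list median of log2(RPKM + 1) was 2.36 in endothelial control replicate 2 and at most 0.11 in the other 5 endothelial libraries. Actin and actomyosin genes had medians of 0.35 and -0.19 (0.0194). Lysosome genes had medians of 0.18 and -1.164 (0.0107) and macrophage markers 0.13 and -0.34 (0.0343), where endothelial control replicate 2 held 2464 RPKM of macrophage markers. Erythroid markers had medians of 0 and -2.96 (3.98e-04), where macrophages held at most 139 RPKM and endothelial arrival replicate 1 held 23.3. Epidermal markers had medians of -3.29 and 0.01 (0.00367), where macrophage control replicate 1 held 1767 RPKM. Photoreceptor and lens markers had medians of -0.01 and 3.05 (0.0107).

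In traction, 6 lists differed. Inflammatory genes had medians of 1.33 in macrophages and -0.29 in endothelial cells (1.19e-04), where endothelial control replicate 2 held 2464 RPKM of macrophage markers and macrophage traction replicate 1 held 3336 RPKM of neutrophil markers. Glycolysis and hypoxia genes had medians of 2.47 and 0.31 (0.0136), and heat shock genes 1.77 and -0.03 (0.0108). Neutrophil markers had medians of 4.22 and -0.47 (6.22e-04). Mesenchyme and cartilage markers had medians of -0.54 and 2.003 (9.27e-04), where endothelial traction replicate 1 held 563 RPKM. Photoreceptor and lens markers had medians of 1.91 and 4.78 (0.0136).

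Photoreceptor and lens markers were high in 1 library each of endothelial arrival, endothelial traction and macrophage traction, and at most 271 RPKM in the other 9 libraries. The ultraviolet opsin gene opn1sw1 (ENSDARG00000045677) stood at 10690.0, 25750.0 and 3251 RPKM in them, and the red opsin gene opn1lw2 (ENSDARG00000044861) at 20520.0, 9928 and 13.0; of the 26 list genes, none of which is in another list, 10 reached 1 RPKM in at least 1 of the other libraries. Reads carried over from either endothelial library into macrophage traction replicate 1 were argued against, since the fraction of photoreceptor reads found there (6.9% and 5.8%) was 23.4 and 24.7 times that of globin reads (0.295% and 0.235%). RNA of photoreceptor cells that passed the sort, meant to remove them, is a candidate source. Pairwise rho (Spearman, 22 genes with reads) was 0.803, 0.875 and 0.911. Ranks cannot single out this source, and opn1lw2 exceeded opn1sw1 in endothelial arrival only. A source outside these libraries and a lesion stage effect, which the partner libraries did not show, stay open and were not tested.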

How the results depend on the processing

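Voom, RPKM without the most abundant gene, the fit without the photoreceptor libraries and list tests under settings other than estimated-correlation camera and fry were chosen after seeing the data. Voom called 212, 467 and 305 genes in macrophage arrival against control, traction against control and traction against arrival, 331, 317 and 274 in the same endothelial comparisons, 37 and 62 in the differences between cell types for arrival and traction, and 1124 between cell types, against 0, 0, 1, 0, 0, 0, 0, 0 and 497 with limma. The 1 gene called in macrophage traction against arrival was lost (0 genes) with quantile normalization, no filter, a pseudocount of 0.1, the 6 libraries of the cell type, the 4 of the comparison, and RPKM without the most abundant gene, and 1 gene was called in macrophage traction against control at 1 RPKM in 2 libraries. With no filter 307 genes were called between cell types, all 307 among the 497, in a test over more genes. Without the 3 libraries with photoreceptor RNA limma called 1021 genes in macrophage traction against control, 1012 in traction against arrival with the 1 gene among them, 107 in endothelial arrival against control, 191 in endothelial traction against arrival, 818 in the cell type difference for traction and 176 between cell types, 170 of them shared. That fit leaves macrophage traction, endothelial arrival and endothelial traction with 1 library each, assumed to vary like the other groups. Leaving out 1 library at a time, under the same assumption, gave 0 to 79 genes in macrophage arrival against control, 0 to 245 in traction against control, 0 to 253 in traction against arrival, 0 to 0 in the 3 endothelial comparisons and both cell type differences, 301 to 522 between cell types, and 49 to 77 list calls. Of the 63 list calls, 45 ended without at least 1 library, 31 without the libraries with photoreceptor RNA and 12 with no filter, and 14 held under every setting but the estimated correlation and fry. With an estimated correlation 2 lists were called and by fry 11, of which 10 were among the 63. Quantile normalization shifted the median difference of all genes by -0.26 in macrophage traction against control, -0.14 in traction against arrival, -0.25 between cell types and -0.42 in the cell type difference for traction, and called 69 lists, 59 of them shared. Replicate numbers gave no clear pairing (correlations of deviations -0.21 to 0.14 over 15 group pairs, 2 above 0.1). As a block they gave 508 genes between cell types (494 shared), 1 in macrophage traction against arrival, 0 in 7 others and 63 lists. Title style (- or _), shared by both endothelial arrival libraries, was not tested. Where list calls ended (168 times over all settings), the mean of the list turned sign 14 times, fell by over 1.5 times 48 times, stayed within that 104 times and was larger 2 times. The list means that turned, with their range over the fits with 1 library left out, were oxidative phosphorylation in macrophage arrival (-0.54 to 2.70) and traction against control (-0.097 to 3.14), cell cycle in macrophage traction against control (-1.06 to 0.21), mesenchyme in endothelial traction against control (-0.41 to 3.86) and arrival (-0.79 to 3.48), erythroid (-0.12 to 5.05), radial glia (-2.67 to 0.027) and glycolysis (-0.20 to 1.44) in endothelial traction against arrival, and photoreceptor markers in the cell type difference for traction (-6.15 to 2.09). Without the libraries with photoreceptor RNA 3 of them turned, to 0.11 (cell cycle), -0.41 (mesenchyme against control) and 0.043 (photoreceptor). None was called in the turned direction; lists were not tested with voom. Of 423 values of named genes, 119 passed newly and 5 no longer passed under voom, 0 and 13 with no filter, and 49 and 26 without the libraries with photoreceptor RNA, where 23 that did not pass lost or turned their sign. Over the fits with 1 library left out these numbers were 49, 42 and 42. No named gene that passed turned its sign. The causes of these changes were not tested except where fewer libraries or more genes give them. A second count scaling and a second count test, planned for count tables, were not run. At the spread of these libraries few 4-fold changes of single genes can be called, so a gene not called is not shown to be unchanged.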

Other observations

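The tests of list calls under exchanged libraries and of carried-over reads were chosen after the results had been seen. Voom was added after seeing the data, and the tests on voom counts and on gene length were chosen after the patterns they address, but not their own values, had been seen. The test on other splits was planned. When 1 library was exchanged between the groups, the glycolysis and hypoxia list was not called in macrophage arrival against control (camera adjusted p = 0.754 and 0.219 for the 2 exchanges) or in traction against control (0.479 and 0.417). Exchanged libraries called the cell cycle list in endothelial traction against control too (0.0226 and 0.0294), and not in traction against arrival (0.794 and 0.625). The erythroid list was called in endothelial arrival against control under both exchanges (0.00747 and 0.0112). In endothelial traction against arrival it had 1.46e-07 and 0.683 under the exchanges against 1.54e-04 in the real grouping, and in traction against control 0.0478 and 0.0583 against 0.135. Over all lists the real grouping gave more calls than both exchanges in macrophage traction against control alone (9 against 7 and 4). In the others an exchange called as many lists or more: 5 and 2 against 5 in macrophage arrival against control, 7 and 4 against 2 in macrophage traction against arrival, and in endothelial cells 8 and 12 against 7 in arrival against control, 9 and 10 against 5 in traction against control and 6 and 12 against 6 in traction against arrival.

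Endothelial traction replicate 1 stood apart in its endothelial markers, with a list median of log2(RPKM + 1) of 0.12 against 3.54 to 5.99 in the other 5 endothelial libraries. In that library the VEGF receptor gene flt1 (ENSDARG00000019371) stood at 0.0842 RPKM and cdh5 at 0.555, whereas kdrl stood at 11.4 and CLDN5 (ENSDARG00000014059) at 108. Macrophage traction replicate 2, which had the most genes at 1 RPKM or more (12938), had list medians above the other 5 macrophage libraries for endothelial junction (2.63 against at most 0.07), angiogenesis (2.66, 0.09), matrix (2.18, 0.2) and adhesion genes (1.92, 0.36), with endothelial markers at 0.16.

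More genes were called between macrophages and endothelial cells than in any other split of the libraries that was drawn. Of 100 splits of the 12 libraries into 6 and 6, the real one called most, 497. The highest of the others called 89 and had 5 macrophage libraries on 1 side.

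Voom on recovered reads called 212 to 467 genes between stages where limma called 0 or 1. In 2 of the 6 stage comparisons, both with macrophage traction, the real grouping gave more voom calls than either exchange of 1 library between the groups (467 against 236 and 215, and 305 against 259 and 203). In the other 4 an exchange gave more, such as 1103 and 441 against 331 in endothelial arrival against control and 414 and 1366 against 274 in endothelial traction against arrival. These counts are in line with a spread between libraries of 1 group as large as that between groups. An effect of the lesion stage on some of these genes stays open.

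Genes with 1 to 20 reads were frequent in endothelial control replicate 1 (10458), endothelial traction replicate 1 (8007) and macrophage arrival replicate 1 (6343), against 1984 to 4899 in the other libraries. Reads scattered along genes whether or not these are expressed may account for them, since over genes with at most 20 reads the reads rose with exon length (median Spearman rho 0.333, with 0.275 and 0.377 in the other 2 libraries), against 0.0876 to 0.202 in the 9 libraries with fewer such genes. Reads carried over from the other libraries in proportion to their levels cannot be told apart from no such reads, since the rho with the summed reads of the other 11 libraries was 0.192 at the median and 0.159 and 0.22 in the others, on both sides of the bound of 0.2. In the 9 libraries with fewer such genes this rho was 0.138 to 0.306, which overlaps these values. The rule for that bound was changed to take in all 3 libraries after the value had been seen. No biological explanation was tested.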
